A study of Homo sapiens with 27 samples.

How the data were processed

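The series measured RNA of MCF7 cells, a luminal breast cancer line with wild-type p53, that carried a vector kept under puromycin selection. Cells were treated for 16 h with doxorubicin at 1.5 µM, Nutlin-3a at 10 µM or the solvent DMSO, per the labels' protocols. Doxorubicin is an anthracycline that intercalates in DNA and poisons topoisomerase II, and Nutlin-3a blocks the binding of MDM2 to p53. Total RNA came from cells in multiwell plates and was purified with a column kit. Subpolysomal and polysomal RNA came from sucrose gradients of cytoplasmic lysates of separate dishes, so total RNA and the gradient fractions differ in culture vessel and extraction as well as in compartment. Each of the 9 combinations of 3 fractions and 3 treatments has 3 arrays, described by the submitters as biological replicates, and each array holds 1 sample labelled with Cy3.

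The scanner files hold spot intensity values that the authors obtained with Agilent Feature Extraction, per the file headers, which name version 10.7.3.1, while the submitters' processing notes name 10.7.7.1. The processed intensity used here had been background-subtracted and detrended within each array and carried no scaling between arrays, per the file headers. The mean spot intensity and the median local background intensity deposited in the same files were used for 1 alternative. The deposited series values are on a log2 scale: each column correlated with log2 of that array's processed signal at r between 0.993 and 1.00 over probes well above background, the column medians lay between 5.86 and 5.91, and all 27 columns had the same lowest value, as after quantile normalisation without centring of genes. The labels do not state that normalisation.

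Each array had 45015 spots, of which 43376 were no controls, for 41000 probes. Between 43 and 102 spots per array carried an outlier flag and were left out, and 0 spots were saturated. Spots of 1 probe were averaged. The main values were log2 of the processed signal minus that array's 75th percentile over probes. Between 43.5% and 63.5% of probes were well above background on an array, and the 75th percentile of the processed signal was 493 to 1706 on total, 177 to 375 on subpolysomal and 626 to 978 on polysomal arrays. The number of arrays limits the precision. Probes were named through RefSeq annotation of GRCh38.p14, used for names only: 27294 by accession, 2383 by current symbol and 454 by older symbol, while 10869 kept the name in the file. Probe coordinates are those of the files, on hg19. Of 29437 gene names, 29 had no complete probe. The probe with the highest mean signal stood for its gene, 6629 tested genes had more than 1 probe, and a gene was tested where that probe was well above background on all 3 arrays of at least 1 group. This left 17292 genes, 13195 of them with a RefSeq symbol.

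Group means were fitted to all 27 arrays with limma 3.58.1 in R 4.3.3 (18 residual degrees of freedom), with statmod 1.5.0 for correlated blocks, and files were read in R with the package data.table, version 1.17.8. Contrasts of the 9 means gave 16 comparisons. P-values are two-sided, moderated by limma and adjusted by Benjamini-Hochberg over genes within a comparison, with calls at an adjusted p below 0.05. "Change" is a log2 difference of group means, and its error is the SE of the fit. A probe not well above background on any array of a group has only a bound there. Its change is given as at least N-fold: the mean of the bright group against the mean, over the dim group's arrays, of the higher of the probe's own signal and the lowest signal among probes well above background.

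23 gene lists were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over lists, where at least 5 members were tested. They were p53 targets (arrest and feedback, apoptosis, and repair, metabolism and secreted factors), mitosis, DNA replication, cytosolic ribosomal proteins, translation factors, RNA-binding proteins, ribosome biogenesis, estrogen response, NF-kappaB targets, interferon-stimulated genes, the unfolded protein and integrated stress response, sterol and fatty acid synthesis, immediate early genes, replication-dependent histones, the nuclear-encoded respiratory chain, noncoding RNAs, selenoproteins with iron-regulated mRNAs, and markers of fibroblasts, leukocytes, basal and luminal breast cells. Each camera result was repeated with an estimated correlation. The design, the lists, the settings to be varied and the rule for named genes were chosen before the data were examined. Which lists are described gene by gene in each comparison was chosen after the results were seen, as were the settings named so in the closing section. The rule named the 6 genes that rose and the 6 that fell most in total and polysomal RNA against DMSO (4 and 4 elsewhere) among called genes with 3 treated and 3 control arrays fully apart and all well above background (interactions without the separation criterion). It left out placeholder names, applied here as names without a RefSeq symbol and LOC or open reading frame names, and added, per list described, the 2 to 4 called members with the largest change, and TP53, MDM2, CDKN1A, MYC, YBX1 and PCBP2 in each treatment comparison.

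Fits were tested on 17292 simulated genes. At 4-fold, 86.4% of changed genes were called in total doxorubicin against DMSO, 75.8% in polysomal nutlin and 57.6% in polysomal minus subpolysomal doxorubicin response. At 2-fold these shares were 17.9%, 35.8% and 1.49%. Of the 86, 96 and 41 calls, 3.49%, 7.29% and 0% were unchanged genes. The data gave 3139, 2637 and 50, so power in the first 2 was not measured.

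Alternatives covered quantile normalisation over all arrays and within fractions, scaling to 7 spike-in probes, the 75th percentile over probes detected on all arrays, normexp background correction with an offset of 50, the deposited series values, 2 other filters on dim probes, the mean of a gene's probes, a fit to the arrays of a comparison alone, array weights, a trended robust prior, replicate, culture and slide blocks, RefSeq-named genes alone, and leaving out each array. The arrays lay on 9 slides of 1 to 4 arrays and were scanned on 1 day. Same-numbered arrays deviated together (every pair's r across genes over 0.1) in 6 comparisons of 2 groups. They were total and subpolysomal doxorubicin against DMSO, polysomal and subpolysomal doxorubicin against nutlin, and polysomal against subpolysomal RNA under DMSO and nutlin. This does not cover differences of responses. The labels do not say that a number links samples.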

Results

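Gene expression was measured on 27 Agilent single-colour arrays of MCF7 breast cancer cells treated for 16 h with DMSO, doxorubicin at 1.5 µM or Nutlin-3a (nutlin below) at 10 µM, with 3 arrays for each of total, subpolysomal and polysomal RNA under each treatment. Of 17292 genes tested, 13195 carried a RefSeq symbol. Changes are log2 differences of group means ± SE of the fit (n = 3 arrays per group) relative to each array's 75th percentile, and adjusted p-values are from limma. Their variance is pooled per gene over 27 arrays, of residual SD 0.17 to 0.61. The median SE was 0.314 for a difference of 2 groups and 0.444 for a difference of 2 responses. Changes under both compounds are measured against the same 3 DMSO arrays of each fraction. The largest rises and falls, and the highest and lowest genes, were taken among called genes with a RefSeq symbol, well above background on all arrays of both groups and with these arrays fully apart. A gene rose or fell where limma called it at an adjusted p below 0.05, and a list counts as called where camera did so at its preset correlation.

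Doxorubicin against DMSO in total RNA asks which transcripts changed when DNA was damaged. CDKN1A, which encodes the cyclin-dependent kinase inhibitor p21, rose by 3.11 ± 0.36 (8.65-fold, n = 3, adjusted p = 2.47e-06), from 2.63 ± 0.52 (SD) to 5.74 ± 0.21. Its probe lies on chromosome 6 at 36654706 to 36654765 (hg19). MDM2, the ubiquitin ligase of p53 (chromosome 12, 69236129 to 69236188), rose by 2.11 ± 0.26 (4.31-fold, adjusted p = 5.98e-06). MYC, a growth-promoting transcription factor (chromosome 8, 128753268 to 128753327), fell by 2.84 ± 0.40 (7.16-fold, adjusted p = 2.23e-05). The mean of its probes changed by -0.90 (adjusted p = 0.0303). TP53 itself (-0.09 ± 0.51, adjusted p = 0.924) and the RNA-binding protein genes YBX1 (0.01 ± 0.38, adjusted p = 0.987) and PCBP2 (0.10 ± 0.24, adjusted p = 0.813) were not called.

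Within these limits the largest rises in total RNA under doxorubicin were those of DPYSL4, a dihydropyrimidinase-like gene (6.01 ± 0.50, 64.6-fold), the transcript ZNF473CR (5.85 ± 0.38), the glutamate receptor subunit gene GRIN2C (5.49 ± 0.35), the smooth muscle actin gene ACTA2 (4.91 ± 0.38), the oxidoreductase gene TP53I3 (4.77 ± 0.37, 27.3-fold) and VWCE, which encodes a secreted protein (4.64 ± 0.39). TP53I3 (chromosome 2, 24300615 to 24302356) went from 0.20 ± 0.02 (SD) to 4.97 ± 0.03. The largest falls were those of the helicase gene PIF1 (-5.53 ± 0.83, 46.2-fold), the cystine transporter gene SLC7A11 (-4.79 ± 0.56), the mitochondrial folate enzyme gene ALDH1L2 (-3.57 ± 0.50) and the metallothionein genes MT1B (-3.58 ± 0.52), MT1X (-3.57 ± 0.52) and MT1H (-3.55 ± 0.45). Metallothionein sequences are similar, so which of them a probe measured is uncertain.

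p53 target genes formed the groups with the most uniform rises in total RNA under doxorubicin. Of 19 tested arrest and feedback targets, 18 rose (19 adjusted over the list alone) and 0 fell, with a median of 2.10 (1.98 above the median of all genes, which was 0.12; camera adjusted p = 4.79e-18, 0.00225 with an estimated correlation). PLK3, a stress-activated kinase gene, rose by 3.17 ± 0.35 and BTG2, an antiproliferative gene, by 2.92 ± 0.32. Of 17 apoptosis targets 13 rose (15 adjusted over the list alone), among them the death receptor gene FAS (3.16 ± 0.27) and the decoy receptor gene TNFRSF10C (2.92 ± 0.23), with a median of 1.61 (adjusted p = 1.74e-14, 0.00283 with an estimated correlation). Of 22 targets for repair, metabolism and secreted factors 18 rose and 1 fell, also adjusted over the list alone, with a median of 1.64 (adjusted p = 1.87e-13, 0.00463 with an estimated correlation). They included the glutaminase gene GLS2 (7.45 ± 0.57; its probe was well above background on 1 of 3 DMSO arrays), the mitochondrial quality control gene SPATA18 (3.57 ± 0.36) and the actin regulator gene CYFIP2 (3.39 ± 0.30).

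Cell division genes fell in total RNA under doxorubicin and DNA replication genes as a list did not. Of 30 mitosis genes 22 fell (28 adjusted over the list alone), with a median of -1.58 (-1.70 relative to all genes; camera adjusted p = 7.21e-16, adjusted p = 0.0841 with an estimated correlation). The mitotic kinase gene PLK1 fell by 3.44 ± 0.57, the kinetochore motor gene CENPE changed by -3.23 ± 0.33 and the checkpoint kinase gene BUB1 by -2.11 ± 0.51 (-1.24 and not called with a slide block, adjusted p = 0.255). Of 30 replication genes 2 rose and 2 fell, also adjusted over the list alone, with a median of -0.33 (adjusted p = 0.167): the polymerase clamp gene PCNA rose by 1.93 ± 0.30. Of 36 ribosome biogenesis genes 12 fell (18 adjusted over the list alone) and 0 rose, with a median of -0.74 (adjusted p = 5.73e-09, adjusted p = 0.116 with an estimated correlation). BOP1, needed for the large ribosomal subunit, changed by -1.89 ± 0.40 (not called with a slide block, adjusted p = 0.0554) and the RNA polymerase I subunit gene POLR1B by -1.44 ± 0.24. Of 28 genes of the unfolded protein and integrated stress response 11 fell, also adjusted over the list alone, with a median of -0.44 (adjusted p = 1.21e-06, 0.00404 with an estimated correlation). CHAC1, a glutathione-degrading enzyme gene, changed by -3.25 ± 0.36, the transcription factor gene DDIT3 by -2.86 ± 0.40, and the serine synthesis gene PSAT1 was at least 6.33-fold lower.

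The median of 58 cytosolic ribosomal protein mRNAs was 0.36 in total RNA under doxorubicin, with 0 called in either direction (camera adjusted p = 0.00139, adjusted p = 0.824 with an estimated correlation), and it became -0.02 under quantile normalisation. The other lists tested in this comparison were not called. Rises and falls among their tested members were 2 and 2 of 38 translation factors, 3 and 1 of 39 RNA-binding proteins, 4 and 3 of 26 estrogen response genes, 3 and 0 of 14 NF-kappaB targets, 3 and 4 of 21 interferon-stimulated genes, and 3 and 1 of 25 sterol and fatty acid synthesis genes. They were 5 and 1 of 24 immediate early genes, 1 and 2 of 15 histones, 1 and 0 of 38 respiratory chain genes, 2 and 0 of 19 noncoding RNAs, and 1 and 0 of 14 selenoprotein and iron genes. Among cell type markers they were 1 and 1 of 5 leukocyte, 1 and 3 of 8 basal and 2 and 0 of 11 luminal markers, and 0 of 4 fibroblast markers, too few for a list test.

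In all, 1569 genes rose and 1570 fell in total RNA under doxorubicin (1117 and 1197 of them at least 2-fold). Scaled to the spike-in probes, 383 rose and 1439 fell, with a median of all genes of -0.20. With slide as a block 1273 were called, 1187 of them shared, and the medians were 1.66 for arrest targets, -1.08 for mitosis, -0.70 for ribosome biogenesis and 0.66 for ribosomal proteins. On the 1 slide that held both groups the medians were 2.07, -1.25, -0.75 and 0.42. The count was 2078 without DMSO 1, 1913 without DMSO 3 and 1964 without doxorubicin 1.

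Nutlin against DMSO in total RNA asks which transcripts changed when p53 was released from MDM2 without a DNA-damaging drug. MDM2 rose by 3.19 ± 0.26 (9.14-fold, n = 3, adjusted p = 2.07e-08) and CDKN1A by 3.06 ± 0.36 (8.33-fold, adjusted p = 2.62e-06). MYC fell by 1.45 ± 0.40 (2.74-fold, adjusted p = 0.0152), a call that was lost without DMSO 1, DMSO 3, nutlin 2 or nutlin 3 (highest adjusted p 0.0687) and with a slide block. Its probes averaged -0.03. TP53 (-1.12 ± 0.51, adjusted p = 0.143), YBX1 (-0.32 ± 0.38, adjusted p = 0.627) and PCBP2 (0.25 ± 0.24, adjusted p = 0.518) were not called.

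The largest rises in total RNA under nutlin were those of TP53I3 (4.93 ± 0.37, 30.4-fold), ZNF473CR (4.83 ± 0.38), ACTA2 (4.73 ± 0.38), GRIN2C (4.57 ± 0.35), the antisense transcript UNC5B-AS1 (4.45 ± 0.40) and DPYSL4 (4.38 ± 0.50). EXO1, a DNA repair exonuclease gene, fell by 4.14 ± 0.36 (17.6-fold, adjusted p = 4.55e-08) and DTL, which encodes a ubiquitin ligase adaptor that acts in S phase, changed by -3.95 ± 0.52. The metallothionein probes of MT1X, MT1B, MT1G and MT1H changed by -4.11 ± 0.52, -4.04 ± 0.52, -3.99 ± 0.52 and -3.96 ± 0.45, with the same uncertainty of identity.

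Of the arrest targets 15 of 19 rose in total RNA under nutlin (18 adjusted over the list alone), with a median of 1.96 (1.83 above all genes, whose median was 0.13; camera adjusted p = 4.11e-18, 0.00255 with an estimated correlation). ZMAT3, an RNA-binding p53 target, rose by 2.96 ± 0.24. Of 17 apoptosis targets 10 rose (13 adjusted over the list alone), among them FAS (3.22 ± 0.27) and the pore-forming BAX (2.24 ± 0.25), with a median of 1.10. Of 22 repair and metabolism targets 16 rose (19 adjusted over the list alone), with a median of 1.63, including SPATA18 (4.07 ± 0.36) and the chloride transporter gene SLC12A4 (3.63 ± 0.34). Both lists were called (camera adjusted p = 4.71e-11 and 1.19e-15, 0.00394 each with an estimated correlation).

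Division and replication genes fell together under nutlin. Of 30 mitosis genes 29 fell (30 adjusted over the list alone), with a median of -2.66 (camera adjusted p = 1.06e-37), and of 30 replication genes 27 fell (28 adjusted over the list alone), with a median of -1.93 (adjusted p = 3.13e-27, 0.00394 for both with an estimated correlation). The mitotic kinase gene AURKB changed by -3.48 ± 0.40 and the kinesin gene KIF2C by -3.37 ± 0.37. Among replication genes the DNA methylation factor gene UHRF1 changed by -3.68 ± 0.62, the origin factor gene MCM10 by -3.47 ± 0.56 and the helicase loader gene CDC45 by -2.78 ± 0.34. Of the stress response genes 13 of 28 fell and 2 rose (14 and 2 adjusted over the list alone; median -0.88, adjusted p = 2.47e-06, 0.00394 with an estimated correlation), with CHAC1 at -3.63 ± 0.36 and DDIT3 at -2.84 ± 0.40. Of 36 ribosome biogenesis genes 5 fell (6 adjusted over the list alone; median -0.50, adjusted p = 7.52e-06, adjusted p = 0.268 with an estimated correlation), among them UTP4 (2.00-fold lower, adjusted p = 0.00736, 0.0954 with a slide block).

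Nutlin raised 10 of 26 estrogen response genes in total RNA and lowered 2 (11 and 2 adjusted over the list alone), with a median of 0.53 (camera adjusted p = 0.0283, adjusted p = 0.269 with an estimated correlation). The estrogen receptor cofactor gene GREB1 rose by 1.63 ± 0.32 and the progesterone receptor gene PGR by 1.30 ± 0.29. Both calls were lost when scaled to spike-ins (adjusted p = 0.147 and 0.233). Of 11 luminal markers 6 rose, also adjusted over the list alone, with a median of 0.75 (adjusted p = 0.0106, adjusted p = 0.268 with an estimated correlation), among them the keratin genes KRT19 (1.14 ± 0.25) and KRT8 (1.04 ± 0.26). KRT19 lost its call when scaled to spike-ins (0.75, adjusted p = 0.178) and KRT8 in 6 of 17 other settings (down to 0.48, adjusted p up to 0.341). Basal markers (3 rose and 2 fell of 8) and leukocyte markers (0 and 1 of 5) were not called as lists. Ribosomal proteins had a median of 0.46 with 3 of 58 rising (0 adjusted over the list alone; adjusted p = 7.55e-06, adjusted p = 0.744 with an estimated correlation), which became -0.02 under quantile normalisation.

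Under nutlin, 1329 genes rose and 1230 fell in total RNA (897 and 954 at least 2-fold). Scaled to spike-ins, 190 rose and 1234 fell, with a median of -0.26. With a slide block 1396 were called, 1088 of them shared, and the medians were 1.84 for arrest targets, -2.10 for mitosis and -1.39 for replication. On the slide that held both groups they were 2.07, -2.76 and -1.65. The count was 1448 without DMSO 1 and 1316 without DMSO 3.

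**Figure D1:**
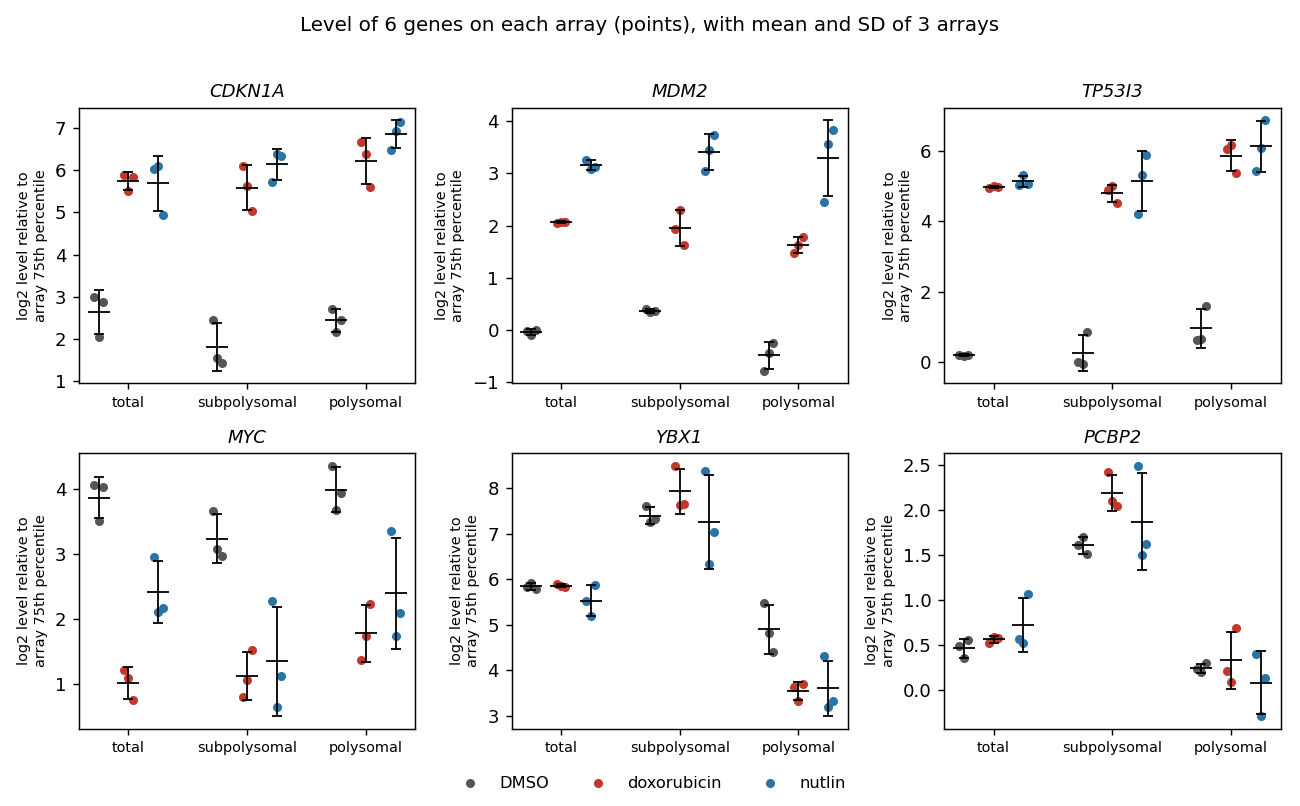
Log2 signal of each array minus its 75th percentile for 6 named genes (y axis), by RNA fraction (x axis) and treatment (colours), with the 3 arrays of each group as points and their mean and SD as bars. CDKN1A in total RNA lies at 2.63 ± 0.52 (SD) under DMSO and 5.74 ± 0.21 under doxorubicin.

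Polysomal RNA, the RNA that sediments with several ribosomes, was compared between doxorubicin and DMSO to ask which mRNAs changed among those being translated. CDKN1A rose by 3.78 ± 0.36 (13.7-fold, n = 3, adjusted p = 1.28e-07) and MDM2 by 2.11 ± 0.26 (4.31-fold, adjusted p = 4.66e-06). MYC fell by 2.21 ± 0.40 (4.62-fold, adjusted p = 0.000283). The mean of its probes changed by -0.85 (adjusted p = 0.0363). YBX1, which encodes an mRNA-packaging protein (chromosome 1, 43167695 to 43167754), fell by 1.35 ± 0.38 (2.55-fold, adjusted p = 0.0127), and all 5 of its probes fell, by -1.33 to -1.62. Its call was lost without polysomal DMSO 1 or doxorubicin 2 (highest adjusted p 0.0852). TP53 (-0.54 ± 0.51, adjusted p = 0.511) and PCBP2 (0.09 ± 0.24, adjusted p = 0.851) were not called.

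Within the same limits the largest rises in polysomal RNA under doxorubicin were those of TP53I3 (4.91 ± 0.37, 30.0-fold), ACTA2 (4.88 ± 0.38), the Golgi protein gene GLIPR2 (4.82 ± 0.40), the transcriptional repressor gene HES2 (4.67 ± 0.45), VWCE (4.49 ± 0.39) and the phosphodiesterase gene PDE4A (4.41 ± 0.47). The largest falls were those of PLK1 (-3.81 ± 0.57, 14.1-fold), ALDH1L2 (-3.49 ± 0.50), CENPE (-3.48 ± 0.33), the carnitine acetyltransferase gene CRAT (-3.46 ± 0.51), the adaptor gene LAT2 (-3.38 ± 0.29) and the neuropeptide gene NMU (-3.36 ± 0.48).

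Among p53 targets in polysomal RNA under doxorubicin, 18 of 19 arrest genes rose (median 2.11, camera adjusted p = 1.57e-21, 0.000829 with an estimated correlation), 16 of 17 apoptosis genes rose (median 1.90, adjusted p = 5.73e-17, 0.00113), and 18 of 22 repair and metabolism genes rose while 1 fell (median 1.72, adjusted p = 1.9e-15, 0.00315). These counts were the same adjusted over the list alone. TP53INP1, an autophagy and apoptosis gene, rose by 3.43 ± 0.30, FAS by 3.48 ± 0.27, the death receptor gene TNFRSF10B by 2.50 ± 0.21 and TIGAR, a regulator of glycolysis, by 3.80 ± 0.31.

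Mitosis genes fell in polysomal RNA under doxorubicin, 24 of 30 (27 adjusted over the list alone), with a median of -1.75 (camera adjusted p = 7.97e-17, adjusted p = 0.0918 with an estimated correlation). Of the replication genes 17 of 30 fell and 1 rose (19 and 2 adjusted over the list alone), with a median of -0.97 relative to that of all genes (adjusted p = 4.95e-07, adjusted p = 0.234 with an estimated correlation). The helicase subunit genes MCM2 and MCM6 changed by -2.21 ± 0.31 and -1.92 ± 0.29. Of 36 ribosome biogenesis genes 14 fell (18 adjusted over the list alone; median -0.76, adjusted p = 2.79e-07, adjusted p = 0.193 with an estimated correlation), among them BOP1 (-2.28 ± 0.40) and the RNA acetyltransferase gene NAT10 (-1.27 ± 0.21; not called with a slide block). Of the stress response genes 10 of 28 fell and 1 rose, also adjusted over the list alone (median -0.27, adjusted p = 0.00646, adjusted p = 0.0926 with an estimated correlation), including the asparagine synthetase gene ASNS (-2.48 ± 0.41; not called with a slide block).

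Of 14 NF-kappaB targets 5 rose in polysomal RNA under doxorubicin (5 rose and 1 fell adjusted over the list alone; median 0.41, camera adjusted p = 0.0476, adjusted p = 0.0564 with a replicate block and 0.234 with an estimated correlation), among them the immune receptor gene CD83 (1.74 ± 0.37) and the inhibitor gene NFKBIE (1.61 ± 0.24). Of 24 immediate early genes 4 rose and 1 fell (5 and 1 adjusted over the list alone; median 0.50, adjusted p = 0.018, adjusted p = 0.545 with an estimated correlation), with the transcription factor genes FOSL1 at 4.17 ± 0.69 (well above background on 1 of 3 DMSO arrays) and KLF4 at 1.33 ± 0.32 (not called with spike-ins). Of 15 replication-dependent histones 6 rose and 1 fell, also adjusted over the list alone (median 0.67, adjusted p = 0.0187, adjusted p = 0.672 with an estimated correlation), among them H2AC25 (1.75 ± 0.29). Of 39 RNA-binding protein genes 3 rose and 6 fell (3 and 7 adjusted over the list alone; median -0.13, adjusted p = 0.687). The splicing regulator gene PTBP2 changed by -1.92 ± 0.35 (not called with a slide block) and the mRNA decay factor gene HNRNPD by -1.91 ± 0.34, while PCBP4, a p53-inducible relative of PCBP2, rose by 1.90 ± 0.34 and the polyadenylation element binding gene CPEB4 by 1.88 ± 0.24. The respiratory chain list was also called (median 0.35, adjusted p = 0.018, 0.729 with an estimated correlation), but was uncalled at -0.33 with a slide block.

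In polysomal RNA under doxorubicin 1700 genes rose and 2038 fell (1140 and 1563 at least 2-fold), and scaled to spike-ins 515 rose and 1342 fell. No slide held both groups. With a slide block 2422 were called, 1706 shared. Medians were 2.76 for arrest targets, -2.88 for mitosis, -1.89 for replication and -1.01 for ribosome biogenesis. Ribosomal proteins, uncalled at 0.14 without it (camera adjusted p = 0.131), were called at -0.70 (1.07e-05).

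Nutlin against DMSO in polysomal RNA gave rises of CDKN1A by 4.41 ± 0.36 (21.3-fold, n = 3, adjusted p = 5.25e-09) and of MDM2 by 3.77 ± 0.26 (13.6-fold, adjusted p = 9.36e-10). MYC fell by 1.59 ± 0.40 (3.02-fold, adjusted p = 0.00671; 0.0534 without nutlin 2 and 0.0823 with the arrays of the comparison alone). The mean of its probes changed by -0.68 (adjusted p = 0.12). YBX1 fell by 1.30 ± 0.38 (2.46-fold, adjusted p = 0.0216), with its 5 probes between -1.30 and -2.32. That call was lost without polysomal DMSO 1, DMSO 2, nutlin 2 or nutlin 3 (highest adjusted p 0.126), or with the arrays of the comparison alone (adjusted p = 0.124). TP53 (-0.41 ± 0.51, adjusted p = 0.669) and PCBP2 (chromosome 12, 53874218 to 53874277; -0.16 ± 0.24, adjusted p = 0.736) were not called.

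The largest rises in polysomal RNA under nutlin were those of UNC5B-AS1 (5.55 ± 0.40, 46.9-fold), the riboflavin transporter gene SLC52A1 (5.32 ± 0.48), TP53I3 (5.16 ± 0.37), the chloride channel accessory gene CLCA2 (5.09 ± 0.46), ACTA2 (4.65 ± 0.38) and HES2 (4.58 ± 0.45). The largest falls were those of the kinetochore genes NDC80 (-5.88 ± 0.46, 58.8-fold) and SPC25 (-5.48 ± 0.56), PLK1 (-5.31 ± 0.57), the recombination gene RAD54L (-5.24 ± 0.46), the spindle gene HMMR (-5.18 ± 0.50) and the condensin gene NCAPG (-5.13 ± 0.43).

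In polysomal RNA under nutlin 17 of 19 arrest targets rose (18 adjusted over the list alone; median 2.27, camera adjusted p = 3.12e-25, 0.00036 with an estimated correlation), 13 of 17 apoptosis targets (15 adjusted over the list alone; median 1.82, adjusted p = 6.38e-18, 0.000664) and 17 of 22 repair and metabolism targets (20 rose and 1 fell adjusted over the list alone; median 1.57, adjusted p = 1.17e-20, 0.000664). Examples are ZMAT3 (3.49 ± 0.24), BAX (2.46 ± 0.25), SPATA18 (4.24 ± 0.36) and CYFIP2 (3.63 ± 0.30). Of the mitosis genes 29 of 30 fell (30 adjusted over the list alone) with a median of -4.07 (adjusted p = 2.5e-49), and of the replication genes 28 of 30, also adjusted over the list alone, with a median of -2.88 (adjusted p = 9.58e-38, 0.000948 for both with an estimated correlation). The ribonucleotide reductase gene RRM2 fell by 4.67 ± 0.60. AURKB changed by -5.55 ± 0.40 and UHRF1 by -5.99 ± 0.62, with probes well above background on 1 of 3 nutlin arrays, and with normexp by only -2.33 and -2.37.

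Of 36 ribosome biogenesis genes 11 fell in polysomal RNA under nutlin, also adjusted over the list alone (median -0.63, camera adjusted p = 3.54e-06, adjusted p = 0.24 with an estimated correlation), with the RNA polymerase I subunit gene POLR1E at -1.81 ± 0.27 (-0.82 and not called with normexp). Of the stress response genes 11 of 28 fell and 1 rose (11 and 2 adjusted over the list alone; median -0.29, adjusted p = 0.0328, adjusted p = 0.198 with an estimated correlation), with SLC7A11 at -3.38 ± 0.56. Of 19 noncoding RNAs 3 fell, also adjusted over the list alone (median -0.59, adjusted p = 0.0227, adjusted p = 0.521 with an estimated correlation). Ribosomal proteins were not called (median -0.17, adjusted p = 0.201).

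Polysomal RNA under nutlin had 1079 genes that rose and 1558 that fell (691 and 1315 at least 2-fold), and 312 and 1003 when scaled to spike-ins. With a slide block 2467 were called, 2064 of them shared, with medians of 2.34 for arrest targets, -4.44 for mitosis and -3.07 for replication. On the 2 slides that held both groups mitosis was at -3.94 and -4.70.

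**Figure D2:**
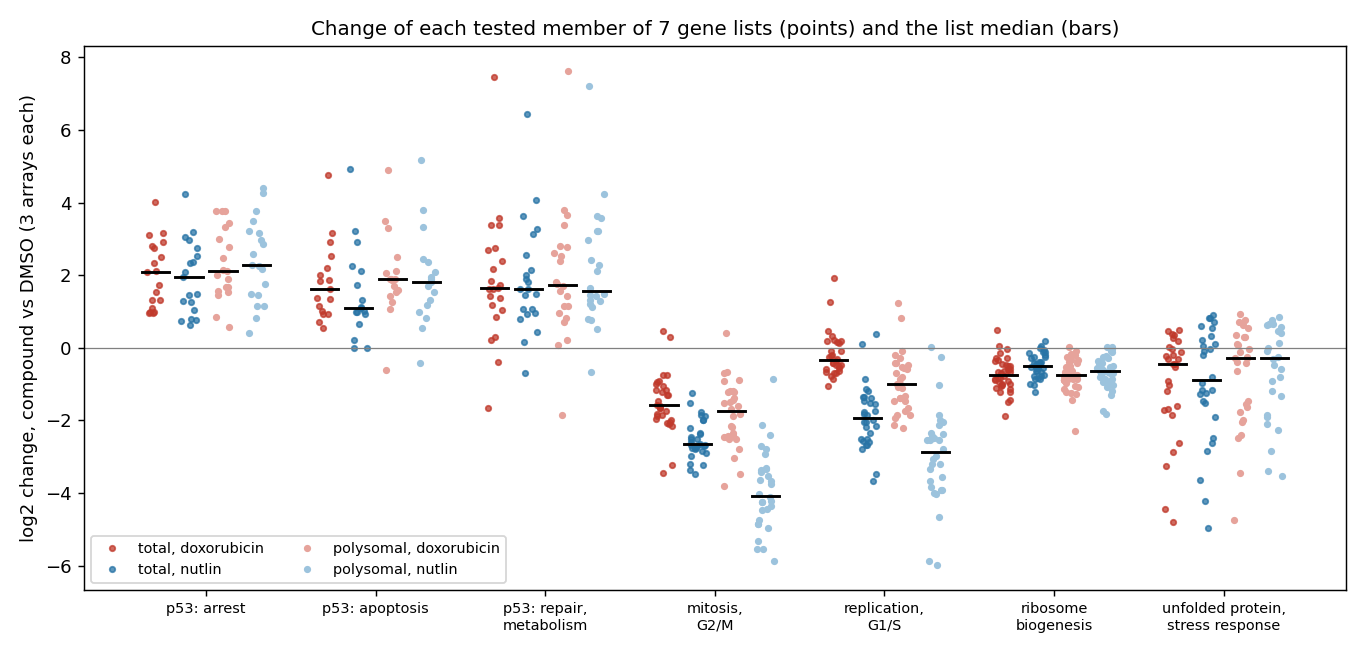
Log2 change against DMSO (y axis) of each tested member of 7 fixed gene lists (x axis) in total and polysomal RNA under each compound, as points, with list medians as bars. In polysomal RNA the mitosis list lies at -1.75 under doxorubicin and -4.07 under nutlin, and the arrest targets lie at 2.11 and 2.27.

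In subpolysomal RNA, which holds messages with few or no ribosomes, CDKN1A rose by 3.78 ± 0.36 under doxorubicin (adjusted p = 2.24e-07) and 4.33 ± 0.36 under nutlin (adjusted p = 1.45e-08), and MDM2 by 1.58 ± 0.26 (not called when scaled to spike-ins, adjusted p = 0.116) and 3.04 ± 0.26. MYC changed by -2.11 ± 0.40 and -1.89 ± 0.40, the latter not called with a slide block. Its probes averaged -0.98 and -0.89. YBX1 (0.53 ± 0.38 and -0.15 ± 0.38, adjusted p = 0.355 and 0.85) and PCBP2 (0.59 ± 0.24 and 0.27 ± 0.24, adjusted p = 0.0962 and 0.52) were not called, and TP53 was not well above background on any subpolysomal array of either compound. Under doxorubicin the largest rises were those of ZNF473CR (6.44 ± 0.38), GRIN2C (5.78 ± 0.35), ACTA2 (4.71 ± 0.38) and TP53I3 (4.53 ± 0.37). The largest falls were PIF1 (-4.64 ± 0.83), the splicing assembly gene GEMIN2 (-3.17 ± 0.25), the tRNA splicing gene TSEN15 (-3.11 ± 0.54) and CDCA7 (-2.99 ± 0.38). Under nutlin UNC5B-AS1 (5.79 ± 0.40), ZNF473CR (5.61 ± 0.38), GRIN2C (5.45 ± 0.35) and the secreted inhibitor gene SERPINF1 (5.29 ± 0.49) rose most. The replication regulator gene TICRR (-4.33 ± 0.44), RAD54L (-4.09 ± 0.46), DEPDC1 (-3.99 ± 0.36) and the kinetochore gene SPC24 (-3.87 ± 0.49) fell most.

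Arrest targets rose in subpolysomal RNA, 18 of 19 under doxorubicin (median 1.96, camera adjusted p = 5.79e-21, 0.000968 with an estimated correlation) and 17 of 19 under nutlin (median 2.30, adjusted p = 1.05e-23, 0.000506), with BTG2 at 3.41 ± 0.32 and 3.04 ± 0.32 and ZMAT3 at 3.07 ± 0.24 and 3.16 ± 0.24. Mitosis genes fell, 24 of 30 (median -1.57, adjusted p = 8.52e-15, adjusted p = 0.134 with an estimated correlation) and 27 of 30 (median -2.80, adjusted p = 7.17e-35, 0.00609). Replication genes fell, 11 of 30 with 1 that rose (median -0.79, adjusted p = 7.69e-06, adjusted p = 0.348 with an estimated correlation) and 22 of 30 (median -1.76, adjusted p = 3.13e-23, 0.00935). Of 11 luminal markers 4 rose under nutlin (median 0.63, adjusted p = 0.0019, adjusted p = 0.175 with an estimated correlation). Counts were 1414 that rose and 1816 that fell under doxorubicin and 1020 and 1329 under nutlin, and scaled to spike-ins 232 and 2447 and 142 and 2915. No slide held both groups. A slide block gave 1317 and 722 (1028 and 642 shared), with mitosis at -2.36 and -3.63. Under doxorubicin the count was 2043 without DMSO 2 and 1710 without doxorubicin 1, and under nutlin 1434 without DMSO 2 and 1415 without nutlin 2.

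Doxorubicin was compared directly with nutlin to ask where the compounds differed. Their doses were 1.5 and 10 µM, so the comparison is of these treatments, and no structural reason is given for any difference. In total RNA, replication genes were higher under doxorubicin in 28 of 30 cases (30 adjusted over the list alone), with a median of 1.67 (camera adjusted p = 3.08e-34, 0.00745 with an estimated correlation). DTL was higher by 3.11 ± 0.52 (8.66-fold, adjusted p = 0.000588, 0.0808 with normexp), UHRF1 by 2.98 ± 0.62, the histone chaperone gene ASF1B by 2.98 ± 0.37, MCM10 by 2.70 ± 0.56 and CDC45 by 2.36 ± 0.34. S100A8, a calcium-binding alarmin gene, was higher by 2.91 ± 0.54. Mitosis genes were higher in 10 of 30 cases (18 adjusted over the list alone; median 0.99, adjusted p = 6.17e-14, adjusted p = 0.287 with an estimated correlation), among them CDC25C (1.84 ± 0.30; not called with normexp). Lower under doxorubicin were THRSP, a lipogenic regulator gene (-3.82 ± 0.57, 14.1-fold), the potassium channel gene KCNJ8 (-3.28 ± 0.58), ANKRD35 (-2.84 ± 0.41) and AFAP1L2 (-2.79 ± 0.75, adjusted p = 0.0247, a call lost with spike-ins and without any 1 of doxorubicin 1 or 3 or of the nutlin arrays). Arrest targets did not differ as a list (0 higher and 1 lower of 19, median 0.05, adjusted p = 0.813). Of 26 estrogen response genes 1 was higher and 3 were lower (median -0.41, adjusted p = 0.0177, adjusted p = 0.287 with an estimated correlation).

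In polysomal RNA, mitosis genes were higher under doxorubicin than nutlin in 27 of 30 cases (median 2.11, camera adjusted p = 1.51e-33, 0.0145 with an estimated correlation) and replication genes in 26 of 30 (median 1.78, adjusted p = 1.51e-33, 0.00861), and in 30 of 30 for both adjusted over the list alone. The mitosis median was 1.22 on the 1 slide that held both groups, 1.61 with a slide block and 0.95 with normexp. SPC25 was higher by 3.88 ± 0.56 (14.7-fold), ASF1B by 3.76 ± 0.37, RAD54L by 3.72 ± 0.46, CCM2L, an endothelial adaptor gene, by 3.58 ± 0.46, RRM2 by 3.57 ± 0.60 and the survivin gene BIRC5 by 3.05 ± 0.48. Calls were lost for CCM2L with normexp (1.10, adjusted p = 0.161), for RRM2 with a slide block (0.0942), and for SPC25 and BIRC5 with the arrays of the comparison alone (0.056 and 0.0825). LAT2 was lower by -3.43 ± 0.29, the platelet-activating factor receptor gene PTAFR by -3.40 ± 0.43, CRAT by -3.37 ± 0.51 and THRSP by -3.28 ± 0.57. Histones were higher in 4 of 15 cases (8 adjusted over the list alone, median 0.80, adjusted p = 0.000192, 0.71 with an estimated correlation). Ribosomal proteins had a median of 0.34 with 0 of 58 called (adjusted p = 0.000417, 0.769 with an estimated correlation). With a slide block their median was -0.31 (adjusted p = 0.00893). In subpolysomal RNA GLIPR2 (2.66 ± 0.40), the cell cycle transcription factor gene E2F2 (2.51 ± 0.35) and SPC24 (2.47 ± 0.49; not called with normexp) were higher under doxorubicin. The imprinted H19 was too (2.51 ± 0.68, adjusted p = 0.0325, up to 0.218 without doxorubicin 1, doxorubicin 2, nutlin 2 or nutlin 3, and lost in 4 of 17 other settings). PTAFR (-3.27 ± 0.43), the asparaginase gene ASPG (-2.81 ± 0.43), the erythrocyte enzyme gene BPGM (-2.78 ± 0.26) and ANKRD35 (-2.63 ± 0.41) were lower. Mitosis genes were higher in 11 of 30 cases there (median 0.99, adjusted p = 2.1e-16, adjusted p = 0.182 with an estimated correlation) and replication genes in 9 of 30 (24 adjusted over the list alone; median 1.00, adjusted p = 2.84e-16, adjusted p = 0.171 with an estimated correlation).

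Between the compounds 600 genes were higher and 511 lower under doxorubicin in total RNA, 819 and 671 in polysomal RNA, and 436 and 453 in subpolysomal RNA. Scaled to spike-ins these were 283 and 135, 347 and 265, and 155 and 55, and the subpolysomal split was 560 and 372 with the percentile over detected probes. A slide block gave 946, 708 and 710 (813, 516 and 589 shared), with replication medians of 1.49, 1.57 and 0.92. Within slides they were 1.61 and 1.78 in total, 1.43 in polysomal and 0.94 and 1.20 in subpolysomal RNA. Counts without 1 array were 583, 603 and 643 in total RNA (without doxorubicin 1, doxorubicin 3 and nutlin 3), 933 and 786 in polysomal RNA (without doxorubicin 1 and 2), and 381, 348 and 460 in subpolysomal RNA (without doxorubicin 1, doxorubicin 2 and nutlin 2).

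The responses to the compounds correlated across genes at r = 0.713 in total, 0.713 in polysomal and 0.741 in subpolysomal RNA (rho 0.685, 0.662 and 0.710), 3 of 7 correlations computed over genes that are not independent. The shared DMSO arrays alone raise such a correlation. In simulations where neither compound changed any gene they gave a mean r of 0.386, 0.473 and 0.481 and a highest of 0.972, 0.969 and 0.947. The observed r does not exceed these. The covariance was 0.479, 0.557 and 0.467, against a mean of 0.0445, 0.0914 and 0.0726 and a highest of 0.242, 0.380 and 0.401 from shared controls. Genes called under both numbered 1385, 1698 and 1403 in the same and 10, 11 and 3 in opposite directions. Of the former 729, 731 and 598 rose and 656, 967 and 805 fell. Independent calls would give 121, 106 and 83 rises and 112, 184 and 140 falls. The highest of 100 simulations had 0, 667 and 21, and 0, 78 and 0. As no gene changed there, shared controls' part in the overlaps stays untested.

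Polysomal RNA compared with subpolysomal RNA under DMSO asks how transcripts were distributed over the gradient before treatment. The mitochondrially encoded COX2 (-4.97 ± 0.56) and COX3 (-4.91 ± 0.39), the mitochondrial-like transcript MTRNR2L2 (-4.84 ± 0.71) and VSIG10L (-5.45 ± 0.39, 43.6-fold, adjusted p = 4.74e-10) were lowest in polysomal RNA. The linker histone gene H1-10 (3.66 ± 0.61, 12.7-fold), the chaperone gene CLU (3.31 ± 0.33), HNRNPAB (3.19 ± 0.32) and the glycosylation gene RPN2 (3.06 ± 0.23) were highest. All 58 ribosomal protein mRNAs were lower in polysomal RNA, also adjusted over the list alone, with a median of -2.64 (camera adjusted p = 6.55e-29, adjusted p = 0.287 with an estimated correlation), RPS12 by -4.03 ± 0.41 and RPS29 by -3.81 ± 0.33. Of 19 noncoding RNAs 16 were lower (median -3.36, adjusted p = 1.74e-07, adjusted p = 0.287 with an estimated correlation), with the host genes SNHG5 (-4.80 ± 0.28) and ZFAS1 (-4.37 ± 0.29). Of 25 sterol and fatty acid synthesis genes 10 were higher (9 adjusted over the list alone; median 0.75, adjusted p = 0.00978, adjusted p = 0.681 with an estimated correlation), among them DHCR24 (2.00 ± 0.29). Of 28 stress response genes 15 were higher and 6 lower (median 0.76, adjusted p = 0.0139, adjusted p = 0.287 with an estimated correlation), with the chaperone genes HSPA5 (2.48 ± 0.40) and PDIA4 (2.26 ± 0.27) higher. Translation factors (12 higher and 19 lower of 38, adjusted p = 0.168) and selenoprotein and iron genes (1 and 7 of 14, adjusted p = 0.0532) were not called, though the latter were with a replicate block (adjusted p = 0.0402).

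Under doxorubicin COX2 (-6.00 ± 0.56), COX3 (-5.85 ± 0.39), SNHG5 (-5.58 ± 0.28) and MTRNR2L2 (-5.58 ± 0.71) were lowest in polysomal RNA, and HNRNPAB (3.24 ± 0.32), the disulfide isomerase gene PDIA6 (3.12 ± 0.24), PTGR2 (3.10 ± 0.23) and the protease gene CTSL (3.06 ± 0.34) highest. Under nutlin VSIG10L (-6.12 ± 0.39), COX2 (-6.11 ± 0.56), MTRNR2L2 (-6.01 ± 0.71) and SNHG5 (-5.82 ± 0.28) were lowest, and the chaperone gene HSPB8 (3.16 ± 0.41), PDIA6 (2.99 ± 0.24), the kinase gene PDK3 (2.82 ± 0.25) and the tetraspanin gene CD9 (2.81 ± 0.27) highest. Ribosomal protein mRNAs were again all lower, with medians of -2.88 and -3.21 (camera adjusted p = 1.23e-31 and 6.53e-32, adjusted p = 0.45 and 0.372 with an estimated correlation). Higher and lower genes numbered 3985 and 5286 under DMSO, 4111 and 5388 under doxorubicin and 4220 and 5655 under nutlin. Each array is scaled to its own 75th percentile, so these are relative amounts: scaled to spike-ins they were 12436 and 647, 13628 and 630, and 14259 and 596, with medians of all genes of 1.81, 2.20 and 2.41. With quantile normalisation more were higher than lower: 4850 and 4321 under DMSO, 4908 and 4221 under doxorubicin and 5157 and 4495 under nutlin. In the deposited series values they were 4755 and 4390, 4827 and 4256, and 5098 and 4523. The ribosomal protein median was -2.47 and -2.86 within slides under DMSO (-2.58 with a slide block), -3.16, -2.97 and -2.61 under doxorubicin and -2.37 under nutlin.

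**Figure D3:**
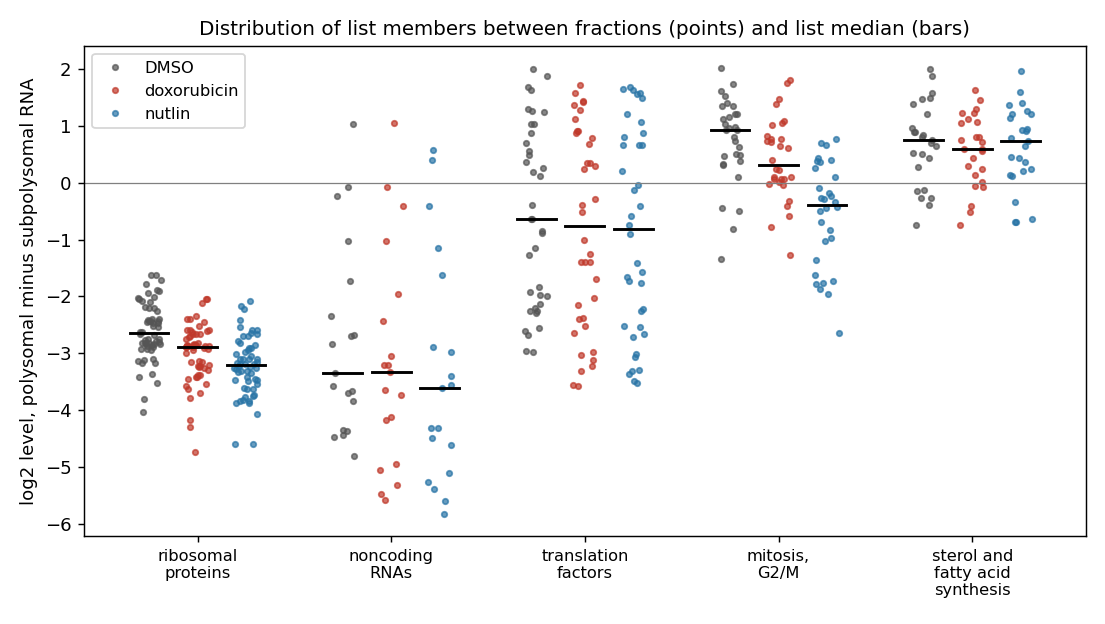
Log2 difference between polysomal and subpolysomal RNA (y axis) of each tested member of 5 fixed gene lists (x axis) under each treatment (colours), as points, with list medians as bars. Ribosomal protein mRNAs lie at -2.64 under DMSO, -2.88 under doxorubicin and -3.21 under nutlin.

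Whether a compound changed polysomal RNA differently from subpolysomal RNA was tested as the difference of the responses. The model leaves out that polysomal and subpolysomal arrays of the same treatment and number can share a gradient, which the labels do not state. A block for such pairs (correlation 0.359) gave 241 genes under doxorubicin and 154 under nutlin. Without it, under doxorubicin 7 genes had a higher and 43 a lower log2 response in polysomal RNA. LAT2 differed by -2.20 ± 0.41 (n = 3 per group, adjusted p = 0.0133; not called without subpolysomal doxorubicin 1 or polysomal doxorubicin 2) and BPGM by 1.97 ± 0.37 (adjusted p = 0.0147; not called without subpolysomal DMSO 1 or subpolysomal doxorubicin 1). The long noncoding RNA LINC03009 differed by 1.56 ± 0.32 (adjusted p = 0.0287), a call lost without any of 9 of 12 arrays. Under nutlin 2 were higher and 33 lower. CDT1, which licenses replication origins, differed by -2.32 ± 0.36 (adjusted p = 0.00397), a call kept without each of the 12 arrays. It was lost when scaled to spike-ins (adjusted p = 0.631), with a slide block (0.274) and with the arrays of the comparison alone (0.159). MCM2 differed by -2.38 ± 0.43 (not called without subpolysomal DMSO 3), MCM7 by -2.05 ± 0.38 (not called without subpolysomal DMSO 1, polysomal DMSO 1 or polysomal nutlin 2) and the cyclin gene CCNB2 by -2.88 ± 0.54 (not called without subpolysomal DMSO 1, subpolysomal nutlin 1, polysomal DMSO 1, polysomal DMSO 2 or polysomal nutlin 2). The other 6 genes also lost their calls when scaled to spike-ins or with normexp. YBX1 was called under neither compound (-1.88, adjusted p = 0.222 under doxorubicin and -1.15, adjusted p = 0.798 under nutlin).

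As lists, mitosis genes had a lower (more negative) response in polysomal than subpolysomal RNA under nutlin (median -1.11, 1 of 30 called, 13 adjusted over the list alone; camera adjusted p = 1.95e-20, adjusted p = 0.0945 with an estimated correlation), as did replication genes (median -0.95, 3 of 30 called, 10 adjusted over the list alone; adjusted p = 5.61e-16, adjusted p = 0.0945 with an estimated correlation). Ribosomal proteins were at -0.61 (0 of 58 called; adjusted p = 4.61e-17, adjusted p = 0.462 with an estimated correlation) and translation factors at -0.39 (0 of 38; adjusted p = 0.000528, adjusted p = 0.462 with an estimated correlation). Under doxorubicin ribosomal proteins were at -0.40 (0 of 58; adjusted p = 5.99e-06, adjusted p = 0.836 with an estimated correlation) and histones at 0.86 (0 of 15; adjusted p = 2.94e-05, adjusted p = 0.836 with an estimated correlation). A slide block left 3 genes called under doxorubicin and 1 under nutlin, where mitosis was at -0.92, replication at -0.87 and ribosomal proteins at -0.17. No slide held all 4 groups.

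Polysomal and total responses correlated across genes at r = 0.715 under doxorubicin (rho 0.626, slope 0.757) and 0.724 under nutlin (rho 0.578, slope 0.796), and polysomal and subpolysomal responses at 0.739 and 0.786 (rho 0.642 and 0.655). Under doxorubicin 967 genes rose and 1001 fell in both polysomal and total RNA and 21 went in opposite directions, and under nutlin 588 rose, 777 fell and 0 were opposite. The response of polysomal RNA exceeded that of total RNA in 3 genes and was lower in 174 under doxorubicin, of which 3 and 22 had a RefSeq symbol. KCNQ1OT1, a nuclear antisense RNA, differed by -3.06 ± 0.69 (adjusted p = 0.027), GREB1 by -2.01 ± 0.46 (adjusted p = 0.027) and LINC03009 by 1.29 ± 0.32 (adjusted p = 0.0496), calls lost without 9, 7 and 10 of 12 single arrays. The pseudogene HERC2P2 differed by -2.04 ± 0.45 (adjusted p = 0.0225, lost without 7 of 12) and SPDYE3, of a duplicated family, by -1.93 ± 0.37 (adjusted p = 0.0077, kept without each of 12). SPDYE3 lost its call in 6 of 17 other settings, among them normexp (-0.91, adjusted p = 1) and the mean of probes (-1.07, adjusted p = 0.466). All 5 calls were lost with spike-ins, normexp or a slide block. Which copy the probes of HERC2P2 and SPDYE3 measured is uncertain. Under nutlin limma called 0 genes, with 1543 at an unadjusted p below 0.05. The count was 3 with quantile normalisation, 7 with it within fractions, 4 with the series values, 1 with the mean of probes, and 5330 and 5570 with array weights gene by gene and over all genes. It was 67 without polysomal nutlin 3, 50 without polysomal nutlin 1 and 40 without total DMSO 2.

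As lists, polysomal minus total responses under nutlin were -1.39 for mitosis (0 of 30 called, 22 adjusted over the list alone; camera adjusted p = 2.85e-16, adjusted p = 0.119 with an estimated correlation), -1.07 for replication (12 adjusted over the list alone; adjusted p = 4.59e-11, adjusted p = 0.119 with an estimated correlation), -0.67 for ribosomal proteins (adjusted p = 2.33e-12, adjusted p = 0.365 with an estimated correlation) and 0.52 for arrest targets (adjusted p = 0.000108, adjusted p = 0.119 with an estimated correlation). With normexp mitosis was at -0.56 and arrest targets turned to -0.0810 (adjusted p = 0.85), and with a slide block arrest targets were at 1.00. Under doxorubicin they were -0.90 for replication (0 of 30, 4 adjusted over the list alone; adjusted p = 5.98e-07, adjusted p = 0.494 with an estimated correlation) and 0.84 for histones (adjusted p = 5.98e-07, adjusted p = 0.494 with an estimated correlation). A slide block left 0 genes called under doxorubicin, and mitosis was at -2.24 and replication at -1.66 under nutlin. Total RNA and gradient fractions came from separate dishes and extractions, which a difference of responses removes only where both treatments were affected alike.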

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

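For the unnamed transcripts all 3 tests, on arrays left out of the choice of transcripts and on nuclear RNAs, were chosen only after the results were seen, as was the margin of 1 SD applied to the medians without 1 array. The other tests were fixed beforehand.

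Differences between fractions in the response to a compound, tested as interactions with limma, singled out 50 genes (polysomal minus subpolysomal, doxorubicin), 35 (the same under nutlin) and 177 (polysomal minus total, doxorubicin). Named genes under doxorubicin were the adaptor gene LAT2 (-2.20), BPGM (1.97) and LINC03009 (1.56) between polysomal and subpolysomal RNA. Under nutlin they were the division genes CCNB2 (-2.88), MCM2 (-2.38), CDT1 (-2.32) and MCM7 (-2.05). Between polysomal and total RNA under doxorubicin they were KCNQ1OT1 (-3.06), HERC2P2 (-2.04), GREB1 (-2.01), SPDYE3 (-1.93) and LINC03009 (1.29). CDT1 and SPDYE3 were called on every omission of 1 of the 12 arrays, while the others lost their call without at least 1. In other settings CDT1 lost its call in 3 of 17 (adjusted p up to 0.631), SPDYE3 in 6 of 17 (up to 1) and each of the others in at least 4.

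The spike-in probes, outside the main measurement, gave a further signal. Relative to them the 75th percentile of total RNA was -2.95 ± 0.01 (SD, n = 3) under DMSO, and it was lower by -0.317 under doxorubicin and -0.390 under nutlin. The labels' protocols do not say whether spike-in was added per cell or per amount of RNA, so no amount of RNA per cell follows, and no biological explanation was tested.

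Of the 174 transcripts lower in polysomal than total response under doxorubicin, 152 had no RefSeq symbol. Of these, 118 were well above background on all 3 polysomal DMSO arrays and 117 on no polysomal doxorubicin array, so the size of their fall was not measured. The 177 calls became 0 with normexp and 50 with spike-ins, so they depend on processing. A slide block gave 0, at a median SE of 0.720 against 0.444. Requiring signal on all arrays left 1 but removes transcripts for falling, so is no test. A single polysomal DMSO array is argued against: among transcripts chosen without the 2 arrays compared and detected in another group, at least 73.3% were well above background on each left-out DMSO array and at most 23.5% on a left-out doxorubicin array. A difference of the DMSO arrays from all treated arrays cannot be told apart. With transcripts chosen without the DMSO arrays compared, the weakest median under nutlin was -1.40, also partly at background, between the values set for and against it. Nuclear RNA in the polysomal DMSO fraction cannot be told apart: MALAT1, NEAT1 and TUG1 had a median of -0.70 and went both ways. A shared response to both compounds stays untested.

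Ribosomal protein mRNAs were at -0.61 in polysomal minus subpolysomal response under nutlin. A single array cannot be told apart as a large part of it. The median was -0.313 without polysomal nutlin 2 and -0.940 without polysomal nutlin 1 (SD over omissions 0.174). 170 other genes matched on subpolysomal DMSO level (median 8.33, list 8.99) were at -0.549. This met the condition set for compression of bright signals. An effect on translation in both sets stays untested.

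Mitosis genes were at -1.11 in the same comparison. The median without 1 array ranged from -1.74 (without polysomal nutlin 1) to -0.898, which argues against a single array as the cause of the fall (SD 0.234), while its size depends on that array. A wider signal range on polysomal arrays cannot be told apart: 148 genes outside the cell cycle lists, matched on change in total RNA and on level, had a median of -0.524, between the values set for and against it. A nutlin effect on how these mRNAs are loaded on ribosomes stays open as untested.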

How the results depend on the processing

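The percentile over probes detected on all arrays, RefSeq-named genes alone, array weights gene by gene and the slide block for lists were chosen only after the results were seen. The limits are few arrays, dim probes (43.5% to 63.5% of probes well above background on an array) and subpolysomal signal, the lowest of the fractions. Omitting an array leaves 2 in its group, whose spread is pooled with the other groups. Below, doxorubicin or nutlin with a fraction means the comparison with DMSO, and "between compounds" means doxorubicin against nutlin. Except where an alternative tests fewer genes, the cause was not tested.

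The replicate block moved no count of called genes by over 1.5 times (total doxorubicin 3510, polysomal doxorubicin 4114) and changed no named gene's call. With it 4 lists lost their call, namely NF-kappaB targets in polysomal doxorubicin (adjusted p = 0.0564), luminal markers in polysomal minus subpolysomal nutlin (0.0569) and arrest targets and RNA-binding proteins in polysomal minus total doxorubicin (0.0556 and 0.058), and 2 gained it, estrogen response and selenoprotein and iron genes in polysomal against subpolysomal RNA under DMSO (0.0402 each). Same-numbered arrays deviated together in 6 comparisons, so the block is the safer reading of those. Over other settings and omissions of 1 array, 7033 results of single genes were the same, 328 lost the call, 5 gained it and 5 turned, and of lists 2781 were the same, 184 lost the call, 135 gained it and 20 turned.

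Scaling to spike-ins gave 1822 and 1424 genes for total doxorubicin and nutlin and 1857 and 1315 in polysomal RNA. Between compounds it gave 418, 612 and 210 in total, polysomal and subpolysomal RNA. Polysomal against subpolysomal RNA had 14258 under doxorubicin and 14855 under nutlin. The differences of responses had 0 (polysomal minus subpolysomal, doxorubicin), 2 (the same, nutlin) and 50 (polysomal minus total, doxorubicin).

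Normexp background correction gave 1569 and 1145 genes in total, 1443 in polysomal doxorubicin, 661 and 572 in subpolysomal RNA, and 356, 673 and 24 between compounds. Polysomal against subpolysomal RNA under nutlin had 4184, and the differences of responses 0, 2 and 0. It also made the changes of dim genes smaller, with mitosis medians of -2.73 in polysomal and -1.66 in subpolysomal nutlin.

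Without a filter on dim probes, 520 genes were called between compounds in subpolysomal RNA, 17533, 17960 and 19119 between polysomal and subpolysomal RNA under DMSO, doxorubicin and nutlin, and 27 in polysomal minus subpolysomal doxorubicin. Testing only probes well above background on all arrays, and so fewer genes, gave 669, 933 and 554 between compounds, 4 and 5 in polysomal minus subpolysomal responses and 1 in polysomal minus total doxorubicin. RefSeq-named genes alone, also fewer, gave 7, 8 and 2 in these last.

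A fit to the arrays of the comparison alone gave 6632 for total doxorubicin, 974 for polysomal and 1129 for subpolysomal nutlin, 1830, 358 and 134 between compounds, 0 in polysomal minus subpolysomal nutlin and 289 in polysomal minus total doxorubicin.

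Array weights gave 11334 and 10121 in total, 7227 and 6892 in polysomal RNA, 6113 and 10619 between compounds in total and polysomal RNA, 323 and 176 in polysomal minus subpolysomal and 4365 and 5570 in polysomal minus total responses. Their estimate had not converged, and gene-by-gene weights gave 12512 and 10115, 6453 and 6323, 4056 in subpolysomal nutlin, 6244, 7512 and 1875 between compounds, 280 and 293, and 4684 and 5330. The trended robust prior gave 22 in polysomal minus subpolysomal nutlin, and the culture block, which treats polysomal and subpolysomal arrays of the same treatment and number as 1 culture, gave 241 and 154 there and 1 in polysomal minus total nutlin.

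The slide block gave 1273 and 1396 in total, 2422 in polysomal doxorubicin, 1317 and 722 in subpolysomal RNA, 708 between compounds in polysomal RNA, 3 and 1 in polysomal minus subpolysomal, and 0 and 3 in polysomal minus total responses. Its median SE, up to 0.720, can cost calls. Polysomal minus total nutlin (main fit 0) had 3 under quantile normalisation, 7 with it within fractions, 4 in the series values and 1 with the mean of probes.

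Lists called by camera with an estimated correlation were 4 of 7 in total doxorubicin, 6 of 11 in total nutlin, 3 of 11 in polysomal doxorubicin, 5 of 8 in polysomal nutlin, 3 of 10 in subpolysomal doxorubicin, 5 of 8 in subpolysomal nutlin, 1 of 7 and 2 of 5 between compounds in total and polysomal RNA, and 0 in polysomal against subpolysomal RNA under DMSO and in every difference of responses. Normexp gave 16 in polysomal nutlin, 10 and 11 in polysomal minus subpolysomal responses and 11 in polysomal minus total doxorubicin, where the slide block gave 12. Between compounds in total RNA quantile normalisation, its form within fractions and spike-ins each gave 3. Spike-ins gave 3 in polysomal minus subpolysomal doxorubicin. Polysomal against subpolysomal RNA under DMSO had 10 with quantile normalisation, 10 with the series values and 13 without a filter.

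The correlation of responses between compounds was 0.744 in total, 0.621 in polysomal and 0.780 in subpolysomal RNA with normexp, and 0.680 in polysomal RNA without a filter. Polysomal and total responses correlated at 0.772 and 0.687 with normexp, 0.636 and 0.612 without a filter and 0.769 under doxorubicin with probes above background on all arrays. Polysomal and subpolysomal responses correlated at 0.647 and 0.686 without a filter and at 0.631 under nutlin with normexp. Genes called under both compounds were 795 in total and 837 in polysomal RNA with spike-ins, 644, 710 and 298 in total, polysomal and subpolysomal RNA with normexp and 1105 in polysomal RNA with probes above background on all arrays.

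Directions turned for ribosomal proteins in total RNA, under doxorubicin and nutlin to -0.0189 and -0.0227 with quantile normalisation, -0.0156 and -0.0214 with it within fractions, and -0.0163 and -0.0070 in the series values. With the slide block they were called at -0.70 in polysomal doxorubicin and -0.31 between compounds in polysomal RNA. At -0.21 and -0.18 in subpolysomal RNA they were not. Respiratory chain genes were there called at -0.63 in subpolysomal and -0.75 in polysomal minus total doxorubicin, not at -0.33 in polysomal doxorubicin. With normexp, medians were -0.28 for RNA-binding proteins, -0.25 for estrogen response and -0.46 for the respiratory chain in polysomal nutlin, -0.46 for the respiratory chain in polysomal minus subpolysomal nutlin, and -0.0810 and -0.0680 for arrest and repair targets in polysomal minus total nutlin. Camera's direction also turned for estrogen response between compounds in polysomal RNA (median -0.13). Among genes, RFC3 in total doxorubicin was at 0.00958 with the mean of probes, PSAT1 in polysomal nutlin at 0.25 and CCNE2 and MKI67 between compounds in polysomal RNA at -0.0717 and -0.26 with normexp, and NUPR1 in polysomal against subpolysomal RNA at 0.00196 with spike-ins.

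Of 321 results of named genes, 83 changed their call in a setting other than an omitted array. Calls lost numbered 41 each with normexp and the slide block, 29 each with spike-ins and the arrays of the comparison alone, 12 without a filter and 10 with the mean of probes.

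Leaving out each array gave 1913 to 3152 genes in total doxorubicin, 1316 to 2648 in total nutlin, 2632 to 3579 and 1817 to 3129 in polysomal, 1710 to 3061 and 1415 to 2277 in subpolysomal RNA. Between compounds it gave 583 to 929, 786 to 2065 and 348 to 900, and between polysomal and subpolysomal RNA 7835 to 8911, 8139 to 8990 and 8871 to 9915. Overlaps were 679 (without total DMSO 3) to 1574, 1172 to 1799 and 791 (without subpolysomal DMSO 2) to 1276. Correlations between compounds were 0.668 to 0.754, 0.659 to 0.747 and 0.699 to 0.769. Polysomal and total responses correlated at 0.642 to 0.744 and 0.637 to 0.762, and polysomal and subpolysomal ones at 0.675 to 0.761 and 0.733 to 0.801.

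Polysomal minus subpolysomal doxorubicin ranged from 24 to 66, with 24 and 28 without subpolysomal doxorubicin 1 and DMSO 1, and 25, 33 and 29 without polysomal doxorubicin 1, doxorubicin 2 and DMSO 3. The same under nutlin ranged from 15 (without subpolysomal DMSO 1) to 107 (without polysomal nutlin 1), with 19 and 18 without polysomal DMSO 2 and nutlin 2. Polysomal minus total doxorubicin ranged from 97 (without total DMSO 1) to 317 (without total DMSO 2), with 103, 100 and 112 without total DMSO 3, doxorubicin 1 and doxorubicin 3, and 102 and 100 without polysomal DMSO 3 and doxorubicin 1. The same under nutlin ranged from 0 to 67 (without polysomal nutlin 3), with 40 and 7 without total DMSO 2 and nutlin 2, and 1, 50 and 9 without polysomal DMSO 1, nutlin 1 and nutlin 2.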

Other observations

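The genes below were chosen after the results were seen, by the rule for named genes applied to further lists. Of 21 interferon-stimulated genes 5 rose and 3 fell in polysomal RNA under nutlin (6 and 3 adjusted over the list alone; median 0.16, camera adjusted p = 0.299). OASL, an antiviral sensor gene, rose by 2.31 ± 0.43 (n = 3, limma adjusted p = 0.000498) and IFIT2, which binds viral RNA, by 1.80 ± 0.43, while the GTPase gene MX2 changed by -1.64 ± 0.27, but by -0.17 with normexp (adjusted p = 0.756). With the arrays of the comparison alone OASL and IFIT2 lost their calls (adjusted p = 0.0508 and 0.0744), and IFIT2 did with spike-ins (0.0579). Of 15 histones 3 fell and 0 rose in total RNA under nutlin (median -0.50, adjusted p = 0.00409, adjusted p = 0.557 with an estimated correlation).

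In subpolysomal RNA under doxorubicin 7 of 24 immediate early genes rose and 1 fell (median 0.51, camera adjusted p = 0.00551, adjusted p = 0.495 with an estimated correlation). Of 14 NF-kappaB targets 6 rose (median 0.42, adjusted p = 0.0165, adjusted p = 0.165 with an estimated correlation). Of 25 sterol and fatty acid synthesis mRNAs 10 were higher in polysomal RNA under DMSO (adjusted p = 0.681 with an estimated correlation), among them DHCR7 (1.87 ± 0.49), SQLE (1.58 ± 0.38) and FDFT1 (1.49 ± 0.28). Of 30 mitosis genes 15 were higher and 1 lower there (median 0.93, adjusted p = 0.00204), and of 30 replication genes 11 and 2 (median 0.60, adjusted p = 0.0139), neither list called with an estimated correlation (adjusted p = 0.679 and 0.681).

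Each comparison has 10 splits of its arrays into groups of 3, so no share under 0.1 can be had. The real split called 3139 genes in total doxorubicin, 2559 in total nutlin, 3738 in polysomal doxorubicin, 2637 in polysomal nutlin, 3230 in subpolysomal doxorubicin and 2349 in subpolysomal nutlin, and the highest other split 0, 0, 3, 399, 1 and 1. Between compounds it called 1111, 1490 and 889 in total, polysomal and subpolysomal RNA, against 0, 30 and 94, and between polysomal and subpolysomal RNA 9271, 9499 and 9875 against 0, 1 and 800. For the polysomal minus subpolysomal response it called 50 and 35 against 0 and 1, and for polysomal minus total 177 against 0 under doxorubicin and 0 against 0 under nutlin. In each of these 1 of 10 splits reached the real count, except the last, where 10 of 10 did.

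Other splits called at least as many lists by camera at its preset correlation in all comparisons tested but the polysomal minus subpolysomal and polysomal minus total responses to nutlin. The real number and the highest other were 7 and 11 in total doxorubicin, 11 and 11 in total nutlin, 11 and 12 in polysomal doxorubicin, 8 and 14 in polysomal nutlin, 10 and 10 in subpolysomal doxorubicin and 8 and 12 in subpolysomal nutlin, with 10, 2, 3, 10, 3 and 6 of 10 splits reaching the real number. They were 7 and 8, and 5 and 9, between compounds in total and polysomal RNA (2 and 6 of 10), 6 and 11 between polysomal and subpolysomal RNA under DMSO (9 of 10), 6 and 7, and 7 and 6, in polysomal minus subpolysomal responses (2 and 1 of 10), and 6 and 9, and 13 and 11, in polysomal minus total responses (4 and 1 of 10). Each other split mixes arrays of both groups and so keeps a part of the real difference. Whether the number of lists called at the preset correlation exceeds chance therefore cannot be decided from these splits.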
